A study of Schizosaccharomyces japonicus with 2 samples.

How the data were processed

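Small RNA of wild-type Schizosaccharomyces japonicus, strain yFS275, was sequenced in 2 libraries from log-phase cells. Per the labels' protocols, RNA of 10 to 40 nt was enriched on a gel from 40 µg of total RNA, and adapters were ligated one after the other. The 5′ adapter needed a 5′ monophosphate and the 3′ adapter a 3′ hydroxyl, per the labels' protocols, so RNA with other ends was not recovered. The products were reverse transcribed, amplified by PCR and sequenced on an Illumina Genome Analyzer, and the labels describe the reads as strand-specific and of 21 to 28 nt.

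The deposited files list, for each library, distinct sequences with 1 aligned place each: supercontig, first and last base, strand, a name and a mapping score. The name joins the rank of the sequence with a whole number that never rises with rank and was read as its number of identical reads. The mapping score deposited by the authors runs from 0 to 37, and a score of 0 was read as a sequence that aligns equally well in more than 1 place. Each such sequence was listed at 1 of its places. Per the submitters' processing notes, BWA was among the tools; its version, its settings and the genome build are not given in the sources used here. Positions refer to the supercontigs numbered 1 to 30 in the deposited files, and are given counting from 1. Neither normalization nor pooling of the libraries is recorded in the deposited files, and the read numbers were used as raw numbers of reads. The labels name the libraries as replicates. Nothing in the labels says that they came from separate cultures, so the spread between them may be technical.

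The table of 5224 genes at hand belongs to another assembly (SJ5), so no coordinate was taken from it and no sequence or annotation was joined to the reads. Base composition at the 5′ end, shares of RNA classes, enrichment in repeats, antisense reads over coding genes, gene orientation and gene lists were planned and were not analysed here. The rule for named items asked for the leading structural RNAs, repeats and genes, and for the 5 densest windows of 1 kb, outside structural RNA and so here outside the block, by the mean of the 2 libraries. Only the last part was used. Any other locus named was chosen after its values were seen. The planned separation of structural RNA was replaced by leaving out bases 1 to 37000 of supercontig 3, a dense region with reads on 1 strand, called the block. This replacement, the classes of windows, the joining of windows into loci and the results on 5′ ends and on stretches without reads were chosen after the data were examined. The test by ranking of differences of start positions and the comparison of spans between classes of loci were added then too. The other tests, and each alternative listed as fixed at the end of this account, were set before the data were examined.

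Reads with a span of 21 to 28 nt were counted in windows of 1 kb by their leftmost base. Outside the block, a window was called dense at 100 RPM (reads scaled to a total of 1000000 outside the block) or more in each library. Dense windows were called both-strand where the minor strand held at least 10% of the reads in each library, one-strand where it held under 1% in each, and otherwise in between. Dense windows with fewer than 2 other windows between them were joined into loci, and a locus was classed by the same limits on its summed reads, so a both-strand locus can hold one-strand windows. Windows were ranked to find how many held 50% and 90% of the reads. Shares within 50 kb of a supercontig end were compared with 1000 circular shifts of the reads along each supercontig (one-sided permutation test), taking the last mapped base as the end. Shares of 23-nt reads per locus were compared between locus classes with a two-sided permutation test of 100000 resamples on the difference of medians, with Benjamini-Hochberg adjustment over the 2 libraries. The correlation between libraries was taken across windows on log2(RPM + 1).

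Pairs of distinct positions of one span on opposite strands were counted by the difference of their start positions. The count at a difference of −2 nt, an overlap of the span minus 2 nt with 3′ overhangs, was divided by the mean of the other differences within 10 nt. Its planned test shifted one strand by 50 to 2000 nt (1000 shifts, one-sided). An added test ranked it among all differences within 50 nt, and its p is the rank over the number of differences. Diverging 5′ ends on opposite strands were counted, whatever their span, by the number of bases between them. Distances from 5′ end to 5′ end on the same strand were counted around the span of the left read, against the distances within 5 nt. The pair count was tested on simulated data: positions were moved by up to 500 nt and 3000 pairs were added. In the simulated libraries 96.8% and 89.2% of added pairs were recovered, and the ratio without added pairs was 0.983 and 1.00. The planned shift test, run here with 200 shifts, gave p = 0.0149 for replicate 2 without added pairs, in a permutation test. It is therefore not a safe test there. The added ranking gave p = 0.891 and 0.287 without added pairs and 0.0099 in both libraries with them, the last being the smallest that this permutation test can give.

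The files held 3086539 reads in replicate 1 and 3492513 in replicate 2. Shares are given with exact 95% Clopper-Pearson intervals where precision matters. The reads carry no molecular identifiers and were amplified by PCR, so intervals cover counting error only. The limit for a count of 0 is 3 reads, which is 9.72e-05% and 8.59e-05% of the reads. For the planned results, the fixed alternatives were each library alone, 22 to 24 nt only, each position with its strand and span counted once, scores above 0 only, windows of 5 kb, ends of 20 kb, a pseudocount of 0.1 RPM and other overlaps. For concentration and supercontig ends, structural RNA kept in was fixed too and was run as the block kept in. All other alternatives were added after the data were examined. Counting distinct positions changes nothing in the pair count, which uses them already. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.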

Results

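Small RNA from log-phase cells of wild-type Schizosaccharomyces japonicus, a fission yeast, was profiled in 1 group of 2 libraries, named replicate 1 and replicate 2. The series set out to isolate and describe the small RNAs of the wild type, so no conditions were compared. Replicate 1 held 3086539 mapped reads from 341792 distinct sequences, and replicate 2 held 3492513 reads from 677769 sequences. Sequences seen once made up 72.1% and 67.7% of these, and the most abundant sequence had 53523 and 20596 reads. Reads of 21 to 25 nt made up 99.7% of each library. Most reads, 89.6% of replicate 1 and 77.8% of replicate 2, came from sequences that align equally well in more than 1 place, so their positions stand for one of several copies.

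With every read counted at its listed place, the most reads lay in a single region at the start of supercontig 3. Bases 1 to 37000, called the block here, held 71.0% of the reads of replicate 1 (95% Clopper-Pearson interval 70.96 to 71.06) and 29.4% of replicate 2 (29.40 to 29.49), or 50.3% ± 29.4 (SD, n = 2) of the reads of 21 to 28 nt. Nearly all of them lay on the minus strand, with 25 of 2191841 reads on the plus strand in replicate 1 and 172 of 1028384 in replicate 2. The minus-strand reads ran from base 1294 to 36234 in replicate 1 and from base 448 to 36240 in replicate 2. They covered 70.1% and 70.6% of the bases of the block. The density of 5′ ends of distinct minus-strand sequences rose and fell with a period of 8499 nt in both libraries.

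The profile for this counted each listed minus-strand sequence once at its 5′ end, whatever its number of reads. It was put on a log scale and smoothed over 20 nt. The period was taken as its distance of highest self-correlation up to 12000 nt, where r was 0.61 in replicate 1 and 0.57 in replicate 2. Among distances from 12 to 20 kb, which played no part in that choice, the profile matched itself best at 17008 nt (r = 0.53) and 17007 nt (r = 0.48), within 10 nt of 2 periods. More than 500 nt from there r was at most 0.32 and 0.30. The numbers of minus-strand reads in the 2 libraries, on a log scale, had r = 0.99 and rho = 0.96 across 74 bins of 500 nt. These bins are not independent replicates. The 3′ end used most lay at base 13634, with 169312 reads or 7.73% of the block in replicate 1 and 85419 reads or 8.31% in replicate 2, and it was shared by spans of 21 to 25 nt. The difference in block share between the libraries is far beyond counting error, but with 1 library behind each value its spread across cultures is not measured. Sequences with several places made up 96.4% and 96.2% of block reads, and among reads with a single best place the block share was 24.9% and 5.04%.

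**Figure D1:**
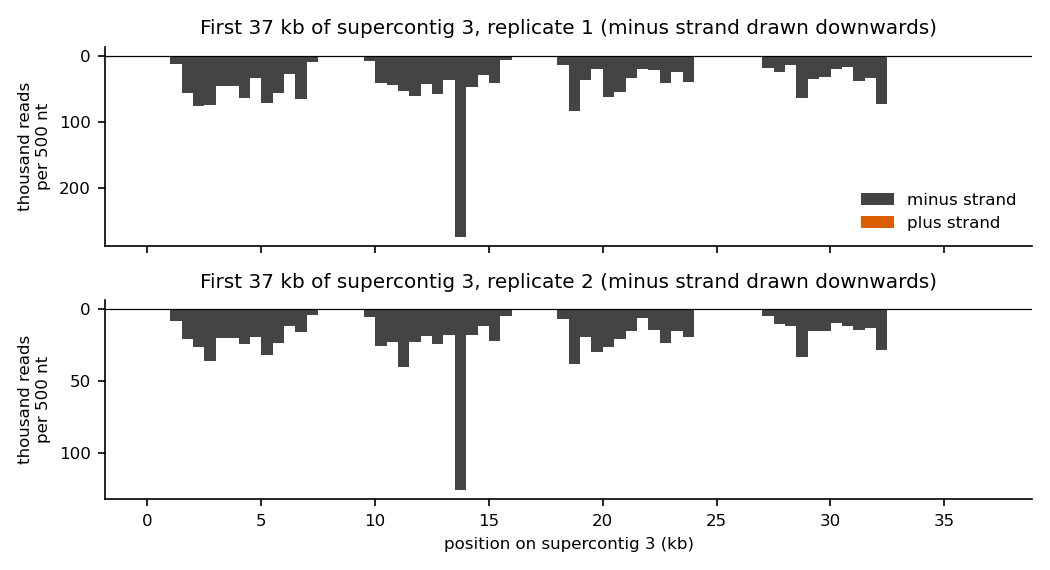
Reads per 500 nt along the first 37 kb of supercontig 3 in each library, minus strand downwards and plus strand upwards, on separate vertical scales. The period of 8499 nt in both libraries was found from the 5′ ends of distinct minus-strand sequences, not from these read numbers. The 25 and 172 plus-strand reads are too few to be seen.

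Mapped spans differed between the regions of the genome. Outside the block, 23 nt was the most frequent span in both libraries, with 25.8% of the reads in replicate 1 and 34.3% in replicate 2. In the block, 21 nt was most frequent, with 23.7% and 25.6%, and 23 nt held 21.96% and 21.41%. As 21 nt is the lower limit of the labelled sizes, and 20 nt held 0.182% and 0.189% of all reads, this is a maximum at a cut edge. Whether shorter RNA was more frequent cannot be seen. Over all reads 23 nt held 26.7% ± 5.25 (SD, n = 2).

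Outside the block, 606 windows of 1 kb reached 100 RPM in both libraries. In 454 of them each strand held at least 10% of the reads in both libraries (203 with reads of a single best place), and these both-strand windows carried 42.7% of the reads outside the block in replicate 1 and 72.5% in replicate 2. Their most frequent span was 23 nt, with 30.7% and 37.2% of the reads. In 41 one-strand windows the minor strand held under 1%, and these carried 22.8% and 7.46% of the reads. Their most frequent span was again 21 nt, the lower limit of the sizes, with 20.2% and 19.2% of reads at 23 nt. The other 111 dense windows lay in between, with 26.4% and 14.9% of the reads.

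The dense windows joined into 136 loci (293 with each position counted once) that held 91.9% and 94.8% of the reads outside the block. By their summed reads, 84 of these loci were both-strand, 22 one-strand and 30 in between. Both-strand loci held 80.2% and 88.7% of the reads outside the block, more than both-strand windows, because some of them contain in-between windows and one-strand windows. The median share of 23-nt reads was 37.04% over both-strand loci and 22.8% over one-strand loci in replicate 1 (permutation test, p = 0.00408, adjusted p = 0.00408), and 36.9% and 20.7% in replicate 2 (p = 4e-05, adjusted p = 8e-05). Loci of one library are not independent replicates, and this comparison was chosen after the classes were seen. The minor strand, taken window by window, held 15.5% and 23.7% of all reads outside the block, or 19.6% ± 5.81 (SD, n = 2).

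**Figure D2:**
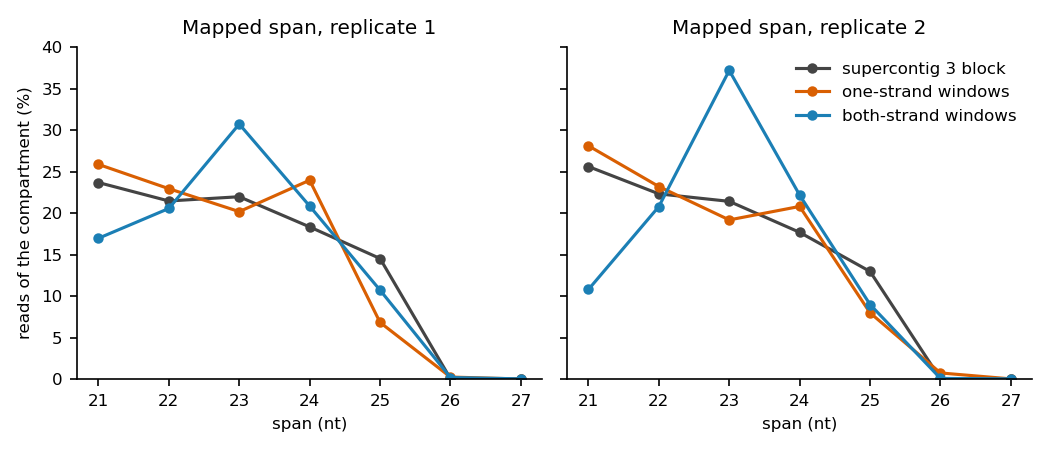
Percentage of reads at each mapped span from 21 to 27 nt in the block, in the 41 one-strand windows and in the 454 both-strand windows, for each library. Both-strand windows peak at 23 nt with 30.7% and 37.2% of their reads, and the other regions are highest at 21 nt, the lower limit of the labelled sizes.

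The libraries held the regions in different proportions. Both-strand windows had a median of 7.47 times as many reads in replicate 2 as in replicate 1 (log2 2.90, interquartile range 2.67 to 3.04). Of these windows, 36 had a ratio under 2, a limit set after the values were seen, and they carried 38.7% of the both-strand reads of replicate 1 and 7.95% of replicate 2. One-strand windows had a median ratio of 1.09 (log2 0.12, interquartile range −0.19 to 1.12). For the block, windows with at least 100 reads in each library were taken, a limit unlike that of the dense windows. These 33 windows had a median of 0.461 (log2 −1.12, interquartile range −1.26 to −0.78). Across 10234 windows outside the block, log2(RPM + 1) had Pearson r = 0.90 and Spearman rho = 0.68, and over the 454 both-strand windows r = 0.79 and rho = 0.83. These correlations are across windows, which are not independent replicates. The chi-square of the window counts was 222 per degree of freedom. It includes reads with several places, whose listed place can differ between files, so it does not alone show 2 separate libraries. The most abundant sequence had 53523 reads in replicate 1 and 20596 in replicate 2, which placement does not change. With reads of a single best place r was 0.73, and with a pseudocount of 0.1 RPM it was 0.76.

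**Figure D3:**
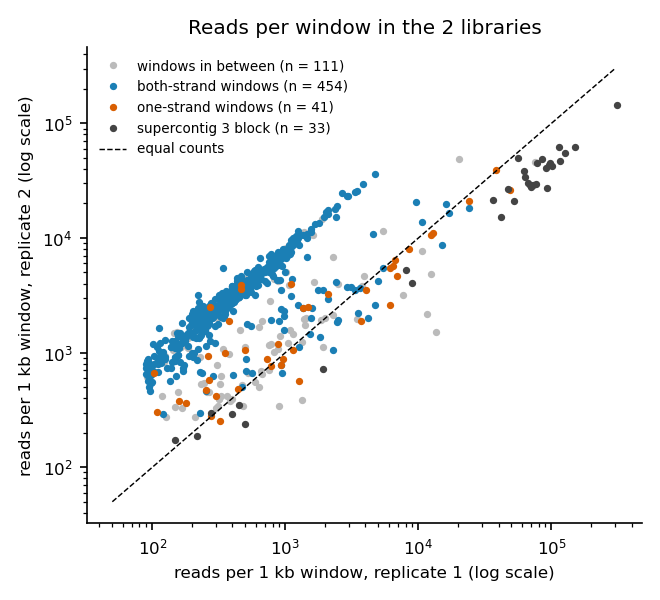
Reads per 1 kb window in replicate 1 and replicate 2, on log scales, with a dashed line at equal counts. Shown are windows of the block with at least 100 reads in each library and dense windows outside it. Most both-strand windows lie along a band with a median ratio of 7.47 and 36 lie under a ratio of 2, with one-strand windows at a median of 1.09 and block windows at 0.461.

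Small RNA outside the block was concentrated in few places. In replicate 1, 29 windows held 50% of the reads and 477 held 90%, of 8348 windows with any read. In replicate 2 these were 106 and 452 of 9549. The number for 50% thus rests on which library is taken, with a mean of 67.5, which was 25 with reads of a single best place and 246.5 with each position counted once. That for 90% was 464.5 ± 17.7 (SD, n = 2). It was 1441.5 with each position counted once, and the libraries differed more with reads of a single best place (946 and 316) and with the block kept in (113 and 412).

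The 5 densest windows outside the block, chosen by the fixed rule, had most of their reads on 1 strand. On supercontig 2, bases 1980001 to 1981000 held 8.46% of the reads outside the block in replicate 1 and 1.86% in replicate 2, of which 97.4% and 93.7% lay on the plus strand. Bases 2392001 to 2393000 of supercontig 2 held 5.46% and 1.06%, with 46.7% and 58.4% of their reads at 21 nt. On supercontig 1, bases 3547001 to 3548000 held 4.34% and 1.60%. These 38600 and 39263 reads came from 49 and 82 sequences that all or nearly all had several places. Bases 1974001 to 1975000 and 1973001 to 1974000 of supercontig 2 held 2.26% and 2.69% of replicate 1 and 1.98% and 0.849% of replicate 2, with 23.8% and 0.0836% of their reads on the plus strand in replicate 1 and 9.14% and 0.340% in replicate 2. What these bases encode was not analysed here.

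The longer loci named here were chosen after their values were seen, and had reads on both strands in sum, with different spans. All but the locus at bases 1827001 to 1852000 of supercontig 2 also held dense windows classed as in between. The 2 with the highest mean share of the libraries lay on supercontig 2, included windows with reads almost only on 1 strand, and had 23-nt shares under the median of both-strand loci. Bases 1973001 to 1985000 held 25.3% and 8.90% of the reads outside the block, with 26.9% and 22.7% at 23 nt, and bases 2384001 to 2393000 held 13.2% and 3.15%, with 13.8% and 14.7% at 23 nt and 40.9% and 35.7% at 21 nt. The locus at bases 39001 to 63000 of supercontig 5 held 3.76% and 10.5% of the reads outside the block, with 58.3% and 57.4% on the plus strand and 37.1% and 38.4% at 23 nt. The locus at bases 4226001 to 4244000 of supercontig 1 held 2.24% and 6.24%, with 41.6% and 39.7% on the plus strand and 41.2% and 40.1% at 23 nt. In these last loci, on supercontigs 5 and 1, reads with several places made up 30.5% to 50.4%. In the other loci named in this paragraph they made up 57.9% to 99.9%, so those positions are less certain. Bases 1793001 to 1821000 of supercontig 1 held 2.63% and 3.77%, with 30.1% and 35.1% at 23 nt, and bases 144001 to 168703 of supercontig 4 held 4.35% and 1.83%, with 12.8% and 17.6% at 23 nt and 40.0% and 15.4% at 21 nt. Bases 1827001 to 1852000 of supercontig 2 held 1.25% and 3.55%, with 48.9% and 50.9% on the plus strand. Bases 1 to 16000 of supercontig 4 held 1.25% and 3.47%, with 26.7% and 26.4% on the plus strand and 39.3% and 40.3% at 23 nt.

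The short supercontigs carried small RNA far above their length. Supercontigs 4 to 30, which make up 4.53% of the mapped length, held 29.9% of the reads outside the block in replicate 1 and 47.7% in replicate 2. Their density per kb was 9.004 and 19.19 times that of supercontigs 1 to 3, and 245 of the 454 both-strand windows lay on them. Within 50 kb of a supercontig end lay 31.4% of the reads in replicate 1 (mean of shifted reads 27.3%, permutation test, one-sided, p = 0.0789) and 53.4% in replicate 2 (43.5%, p = 0.00500, adjusted p = 0.00999). On the 4 supercontigs of 100 kb or more these shares were 15.8% (10.8%, permutation p = 0.0789) and 28.8% (13.7%, permutation p = 0.00500). All reads of the shorter supercontigs lie within 50 kb of an end under every shift, so their part of the shares was fixed in advance. The comparison over all supercontigs and that over the 4 longer ones are therefore the same test, with the same p-values. The share at ends was above the mean of the shifted reads in both libraries and passed the test in replicate 2 alone, and within 20 kb of an end neither library passed (permutation p = 0.111 and 0.118).

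**Figure D4:**
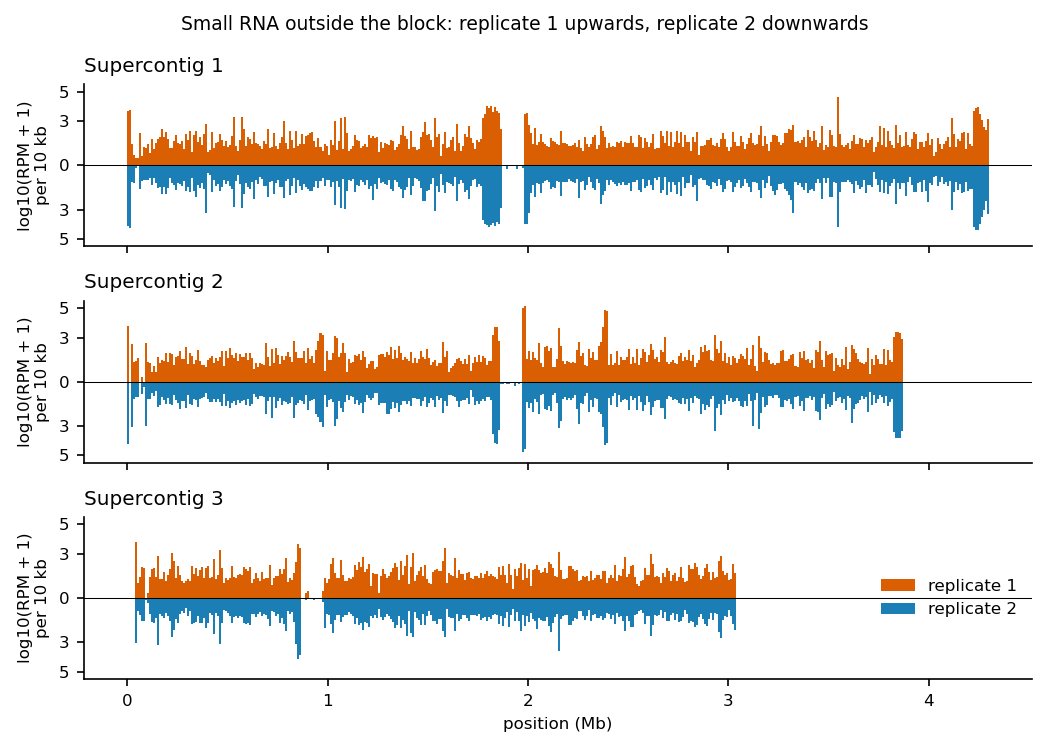
Reads outside the block per 10 kb along supercontigs 1, 2 and 3, as log10(RPM + 1), with replicate 1 upwards and replicate 2 downwards. The longest stretch nearly without reads on each supercontig, of 119 to 120 kb, lies next to dense bins.

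Reads on opposite strands overlapped by their span minus 2 nt, with 3′ overhangs, more often than at neighbouring differences of start. This is the geometry of a duplex with 2-nt 3′ overhangs on each side, which Dicer, the nuclease that cuts double-stranded RNA, leaves. The same overlap length with 5′ overhangs was counted among the neighbours. Outside the block, replicate 1 had 2629 pairs of positions with the 3′ overhangs. The mean was 1629 ± 143 (SD over 20 neighbouring differences), a ratio of 1.61. Replicate 2 had 21563 pairs against 15502 ± 942, a ratio of 1.39. The count was the highest of the 21 differences at each span from 21 to 25 nt in both libraries. Among reads with a single best place the ratios were 1.77 and 1.49.

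The planned shift test gave p = 0.000999 and the ranking among 100 other overlaps gave p = 0.0099 in both libraries, each the smallest that these permutation tests can give. The shift test also passed in replicate 2 on simulated reads without added pairs, so the ranking is the safer of the tests. Overlaps of the span minus 1 nt, again with 3′ overhangs, and of the full span lay below their neighbours, at mean ratios of 0.864 and 0.876. In the sparse windows the ratios were 1.42 in replicate 1, from 23 pairs (ranking, permutation p = 0.208), and 1.43 in replicate 2, from 381 pairs (permutation p = 0.0099).

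Diverging 5′ ends on opposite strands, counted after the first result was seen, lay most often with 2 nt between them. There were 6371 such pairs in replicate 1 against a mean of 3862 at neighbouring gaps, a ratio of 1.65, and 33450 against 23611 in replicate 2, a ratio of 1.42. This was the highest of the 81 gaps counted up to 40 nt on either side in both libraries (permutation p = 0.0123, the smallest possible). Reads following each other on the same strand at a distance of their own span were 1.21 and 1.14 times as frequent as at neighbouring distances outside the block, and 1.06 times in the block in each library.

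**Figure D5:**
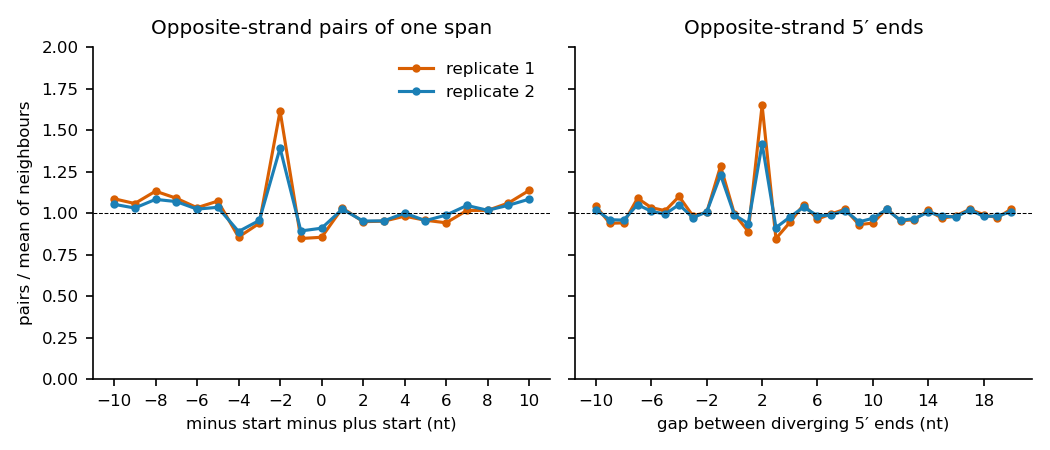
Pairs of positions outside the block divided by the mean of their neighbours, by the difference of start positions for opposite-strand reads of one span and by the gap between diverging 5′ ends on opposite strands. The peaks at −2 nt (ratios 1.61 and 1.39) and at a gap of 2 nt (1.65 and 1.42) stand above all neighbours in both libraries.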

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

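Of the tests in this part, those on the number of amplified sequences and on the most abundant loci were set before their results were seen, and those on strand, period, size selection, mixing ratio, 3-nt steps and 5′ gaps after. The ratio for reads with a single best place was computed as intended from the start, but its use and bounds as a test of placement were set after. Reads shorter than the labelled sizes, which the windows, loci and pairs leave out, numbered 5634 in replicate 1 and 6695 in replicate 2, or 0.183% and 0.192% of the reads. Sequences whose rank has no line in the list of mapped sequences numbered 49619 in replicate 1 and 162491 in replicate 2, or 12.7% and 19.3% of ranks. They carried at most 115801 and 314952 reads, an estimated 3.61% and 8.27% of each library. No control library was at hand, so both were set against a count of 0.

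The block of supercontig 3 held reads of 1 strand in a repeating profile. A few over-amplified sequences would put most reads at few places, but the 10 most abundant 5′ positions held at most 12.8% of its reads. Dicing of a double-stranded precursor would leave reads on both strands, and at most 0.0167% lay on the plus strand. A candidate explanation that stays open is that the reads derive from one unit present in tandem copies. The profile of 5′ ends of distinct sequences also matched itself best at a distance within 10 nt of 2 periods. That distance was sought from 12 to 20 kb, a range that played no part in finding the period. The correlation is one of 5′ ends of distinct sequences, not of read coverage, and no base sequence was compared. Breakdown of an abundant long RNA was not tested against processing of a small RNA.

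The block share differed between the libraries, 71.0% against 29.4%. With each position counted once, the test set for over-amplification of a few sequences, the shares still differed by 2.58 times. That count cannot decide alone, since distinct positions depend on the reads left for each region. They numbered 45310 and 37243 in the block and 178119 and 437152 outside it. The 10 most abundant 5′ positions held 11.9% and 12.8% of block reads, so these few positions do not carry the difference. A difference in size selection as the whole cause is argued against, since at 23 nt alone the shares differed by 3.27 times (67.7% against 20.7%). Mixing of 2 kinds of RNA in one proportion per library stays open: over both-strand windows the log2 ratio of the libraries had an interquartile range of 0.37 (0.367438) and its median lay 4.02 above that of the block. Against a single mixing ratio, one-strand windows had a wider range (1.31) around a level of their own (median 0.12), and 36 both-strand windows with 38.7% of the both-strand reads of replicate 1 had a ratio under 2. No biological explanation was tested, because the labels put both libraries in 1 group, and a difference in breakdown of RNA between the libraries stays open.

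Opposite-strand reads overlapped by their span minus 2 nt, with 3′ overhangs, more often than at neighbouring differences of start. Random placement of repeated sequences is argued against, since reads with a single best place had a ratio of at least 1.49, and so are a few abundant loci, since without the 10 loci of most reads it was at least 1.41. Against start differences that lie multiples of 3 nt away it was at least 1.34, so the 3-nt steps in the pair counts do not account for it. Cuts of double-stranded RNA with 2-nt 3′ overhangs are a candidate explanation that also places 2 nt between the diverging 5′ ends on each side of a cut, and that gap stood at 1.42 or more times its neighbours. Sequence preferences in ligation were not tested, so the link to Dicer is a hypothesis.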

How the results depend on the processing

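Added after the data were seen were all alternatives on the block share, the share with several places, the loci, the window classes, the same-strand distances and the flanks of the long stretches nearly without reads, the block left out of the spans or kept in for strand balance and correlation, and other backgrounds, scores of 0 and leading loci left out for the pair count. Of 80 alternatives to 13 results, 56 met the criterion for no change: for a test the same direction and the same call over both libraries together, for a count a change within 1.5 times, and otherwise a change within 1 SD or, for the correlation, 0.05. Some of the 56 were fixed in advance: with 2 libraries, each alone lies within 1 SD of their mean for results given as a value. A test that passed in both libraries also keeps its call with either library alone. The cause of the other changes was not tested unless said. The share of 23-nt reads kept within the spread throughout. The excess of opposite-strand pairs held in each library alone, at 22 to 24 nt, with a single best place, with several places and without the leading loci, with mean ratios from 1.39 to 1.63. At overlaps of the span minus 1 nt and the full span it turned to 0.864 and 0.876. Windows holding 50% of the reads numbered 67.5 on average, 29 to 106 with 1 library left out, 25 with a single best place, 37.5 with the block kept in and 21.5 in windows of 5 kb, which are fewer by construction. Those for 90% went from 464.5 to 262.5 with the block (113 and 412), 631 with a single best place (946 and 316) and 139 in windows of 5 kb. The correlation between libraries fell to 0.726 with a single best place and 0.760 with a pseudocount of 0.1 RPM. Counting each position once gave 246.5 windows for 50%, 1441.5 for 90%, a correlation of 0.767, 29.2% on the minor strand, 14.1% in the block, 59.2% with several places and 293 loci. A single best place left 15.0% in the block and 203 both-strand windows. With the block kept in, 10.6% lay on the minor strand. The share at supercontig ends, 42.4% on average, was 31.4% to 53.4% with 1 library left out; it passed in both libraries when positions were counted once (47.5%) and with the block, which lies at an end, kept in (73.7%). Within 20 kb of an end it was 26.5% and replicate 2 also lost its call (permutation p = 0.118). The share beside the long stretches nearly without reads fell from 42.9% to 26.9% with positions counted once (22.5% and 31.3%) and still passed in both libraries. In the sparse windows the ratio of 1.42 in replicate 1 rested on 23 pairs and missed the threshold, while 1.43 in replicate 2 rested on 381 and passed it. Alternatives that need a genome or annotation were not run.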

Other observations

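All tests in this part were chosen after the results were seen. The longest stretch nearly without small RNA was taken on each of the 3 large supercontigs, and it was bordered by dense loci on at least 1 side. The next longest stretches were not examined. The longest run of 1 kb windows with at most 5 reads of both libraries together was 120 kb on supercontig 1 (bases 1861001 to 1981000), 120 kb on supercontig 2 (1853001 to 1973000) and 119 kb on supercontig 3 (869001 to 988000). The stretches held 5 reads in replicate 1 and 22 in replicate 2. Within 50 kb on either side, which is 2.68% of the length of these supercontigs, lay 44.9% of their reads outside the block in replicate 1 and 40.9% in replicate 2. With each position counted once these shares were 22.5% and 31.3%. Stretches of the same size placed at random positions had means of 2.35% and 2.496%, and no placement of 1000 reached the observed share (permutation test, one-sided, p = 0.000999, the smallest possible, in both libraries). The stretches were picked from the same reads and random placements need not be quiet, so p does not allow for that choice. Whether the stretches hold unresolved bases or repeats whose reads were placed elsewhere was not analysed here.

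The flanks were unequal. On supercontig 2 the right flank held 25.3% of all reads outside the block in replicate 1 and 8.93% in replicate 2, and the left flank 1.27% and 3.59%. On supercontig 1 the left flank held 3.30% and 4.72% and the right flank 0.737% and 2.01%. On supercontig 3 the left flank held 0.762% and 2.11%, and the right flank 0.0783% and 0.0422%.

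The gaps between diverging 5′ ends on opposite strands rose and fell in steps of 3 nt. From 4 to 39 nt, 12 of 12 gaps in step with the peak at 2 nt were higher than both of their neighbours in each library, against the 4 that chance would give for independent counts. They exceeded the neighbours by a factor of 1.049 in replicate 1 and 1.036 in replicate 2. With reads of a single best place 11 and 10 of 12 were higher. Base composition with codon structure was not examined, since no sequence was used.

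Distinct 3′ ends outnumbered distinct 5′ ends in the both-strand windows by 1.17 times in replicate 1 and 1.21 times in replicate 2. In the block this ratio was 0.998 and 0.990, and in the one-strand windows 0.992 and 1.00.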
